A study of Mus musculus with 7 samples.

How the data were processed

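The data came from mouse leukaemia cells (BALB/c background) carrying mutant CSF3R and CEBPA, grown for 48 h with GSK-LSD1 at 4 nM or with DMSO as the solvent control. Chromatin was immunoprecipitated for H3K4me1, H3K4me3 and H3K27Ac with a commercial ChIP kit and sequenced as Illumina libraries, per the labels' protocols. There were 6 immunoprecipitated libraries and 1 input library. The read aligner Bowtie and the mouse build mm10 (GRCm38) are named, per the submitters' processing notes; the version of Bowtie is not given in the sources used here. The authors combined the 3 marks of each treatment and deposited, per the labels, 1 segmentation per treatment, in which each segment carries a state from E1 to E6. The tool that made the segmentation, how signal was turned into present or absent marks, whether both treatments were fitted together, how the input was used, and which marks define each state are not given in the sources used here. These steps can change the measurements: a state is a thresholded call, so a mark just under the threshold is absent, and a library with more reads or a cleaner precipitation passes the threshold in more places. Reads and signal tracks were not analysed here. The deposited values are state labels, not counts, so depth is unknown and no count model applies.

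The segments lay on a 200 bp grid, and each segmentation was expanded to bins. There were 136061 segments in DMSO and 162731 in GSK-LSD1. Main results used chromosomes 1 to 19 and X, 13168874 bins or 2633.77 Mb in each. State roles were set in DMSO before any comparison. Background was the state with the largest coverage. A TSS-type state was to have at least 10 times its genome share at transcription start sites. The gene table used here (RefSeq, GRCm38 assembly, 21631 protein-coding genes on these chromosomes) gave no strand, so both ends of each gene were used in place of the start. The limit was changed to 5.5, the average of 10 at the start and 1 at the other end. This change was made after the values had been seen, and it decides whether E6 is counted, so E5 alone was run as an alternative. State numbers were to be compared between segmentations only if each state overlapped its own number most, relative to chance. E1, E2 and E4 did not meet this, so roles carry the main comparison and comparisons by single number are additions. The roles rest on numbers too, since E3, E5 and E6, as set in DMSO, kept their roles in GSK-LSD1. In GSK-LSD1, E5 and E6 were at 10.1 and 7.85 times their genome share at gene ends, both above 5.5. E3 again had the largest coverage, 70.1%.

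Shares of bins, bins gained, lost and kept, and their overlap (Jaccard) were computed for marked chromatin, meaning every state except background. A bin was distal if more than 2.5 kb from every end of an annotated gene of any type (49554 genes). Gene windows were the union of the 20 kb either side of both gene ends, at most 80.4 kb after rounding to bins. A window can thus include the ends of neighbouring genes. For the 15 gene lists, fixed before the data were examined, the median change was placed among 10000 random lists of the same size, matched on the DMSO area of the same states in the same windows (none, then 10 quantile bins). A list outside the central 95% of the random lists was said to stand apart. Of 232 list entries, 229 were matched to the gene table; Azu1, Mx1 and Mx2 were not, and Emr4 was matched as Adgre4 through a synonym. The rule for named genes was also fixed beforehand. It took the 4 members of each list with the largest change in marked area, members that gained or lost a TSS-type end, Cebpa, Csf3r, Kdm1a and Gfi1, the 12 largest increases and 12 largest decreases over all protein-coding genes, and the 8 longest gained and 4 longest lost regions. The same rule was applied to TSS-type area after the data were seen. Some genes that the rule takes are not reported here. Further list members were named after their values had been seen, to show the range in a list. Shares have 95% Wilson intervals. Bins, genes and chromosomes are not replicates, and no p-value was computed.

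The window and list calculations were tested on simulated data, in which the DMSO segmentation was compared with itself after TSS-type gains of 2000 or 4000 bp were planted in 200 of 21631 genes. The median changes came back as 2000 and 4000 bp, and 20 of 20 lists of 15 such genes lay above the central 95% at either size. Of 200 lists without planted gains, 5 lay outside it. Boundaries of TSS-type regions were also shifted at random by at most 200 bp, and the other genes were given no gain. In the real comparison 14296 genes had more TSS-type area. The test thus checks the calculations, and it does not show how the percentiles behave under so general a gain. Alternatives covered the sequences used, short segments, E2 as background, boundary shifts, the distal limit, window size, the genes, the limit for TSS-type states, matching, mean against median, and each chromosome left out. Analyses that need the genome sequence (motifs and base composition of gained regions) were not run, since no sequence was used here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.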

Results

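Leukaemia cells from mouse bone marrow, made by retroviral expression of mutant CSF3R, the receptor for granulocyte colony-stimulating factor, and mutant CEBPA, a transcription factor of granulocytic commitment, were treated for 48 h with 4 nM GSK-LSD1 or with the solvent DMSO. GSK-LSD1 inhibits LSD1 (gene symbol Kdm1a), a demethylase of histone H3 lysine 4 that works with the CoREST complex and the repressor GFI1. Chromatin immunoprecipitation and sequencing was done for 3 histone marks in each treatment: H3K4me1, which is typical of enhancers, H3K4me3, which is typical of promoters, and H3K27Ac, which is typical of active regulatory elements. Of the 7 libraries, 6 were immunoprecipitates and 1 was input DNA, so each mark had 1 library per treatment. The measurement compared here was the authors' segmentation of the genome into 6 chromatin states, E1 to E6, deposited once per treatment. No replicates exist, so no test of treatment could be made and no p-value is given. The values compare these 2 segmentations. The spread over chromosomes is given as a description, 95% Wilson intervals cover counting error only, and the sequencing depth is unknown because the segmentations hold no counts. Which marks define which state is not given in the sources used here, so states were described by where they lay. E3 covered most of the genome and was taken as background. E5 and E6 were concentrated at the ends of protein-coding genes, at 13.3 and 9.45 times their genome share in DMSO, and are called transcription start site (TSS) type. E4, E1 and E2 were at 2.86, 1.40 and 1.24 times theirs.

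The first question was how the chromatin landscape differed after LSD1 inhibition. States E1 and E6 covered far more of the genome in GSK-LSD1 than in DMSO. Values by state number are additions to the planned comparison of roles. Relative to chance, E1, E2 and E4 did not overlap their own number most. A number need not stand for the same marks in both segmentations. E6 went from 0.217% to 2.08% of chromosomes 1 to 19 and X, a ratio of 9.58, and E1 from 0.483% to 4.72%, a ratio of 9.78. The ratio was above 1 on 19 of 19 autosomes for both states, with a mean of 9.84 ± 1.76 (SD, n = 19 autosomes) for E6 and 10.5 ± 2.94 for E1. E4 and E5 covered less, at ratios of 0.814 and 0.774 (below 1 on 19 of 19 autosomes, but 1.34 and 1.10 on chromosome X), and the broad state E2 went from 21.3% to 19.3%. Counting E5 and E6 together, TSS-type chromatin went from 57.8 to 95.2 Mb, a ratio of 1.65 ± 0.0514 over the 19 autosomes. That direction rests on E6: with E5 alone as the TSS-type state the ratio was 0.774. All marked states together went from 26.7% to 29.9%, and from 5.44% to 10.6% when E2 was counted as background.

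**Figure D1:**
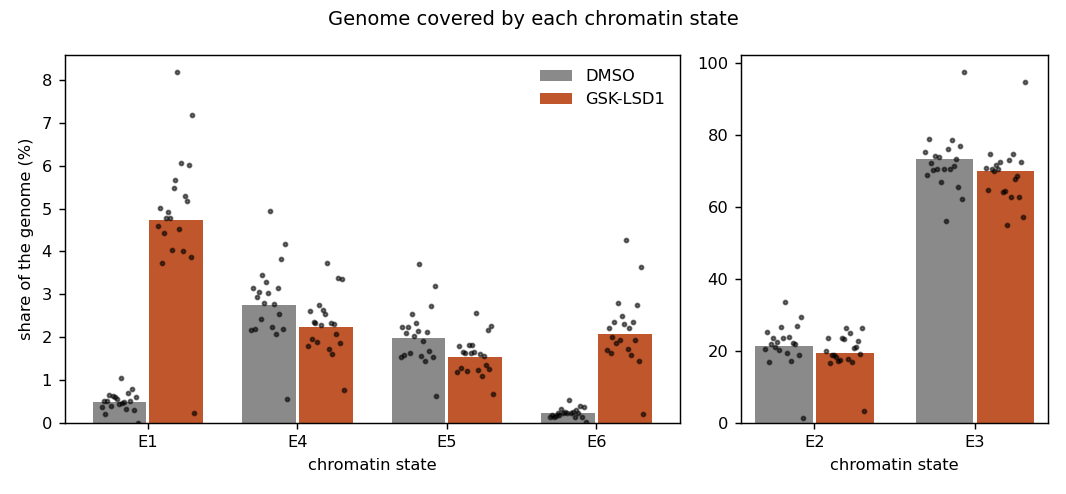
Share of chromosomes 1 to 19 and X (percent, y axis) covered by each chromatin state (x axis) in DMSO (grey bars) and GSK-LSD1 (orange bars); points are the 20 single chromosomes. E1 went from 0.483% to 4.72% and E6 from 0.217% to 2.08%, while E4 and E5 covered less in GSK-LSD1.

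The enlarged E1 and E6 area came mainly from chromatin that was already marked: 3.92% of the E1 bins and 0.334% of the E6 bins in GSK-LSD1 had been background in DMSO. Of the 200 bp bins, 81.8% had the same state number in both segmentations, but 8784528 of these 10769315 bins were background in both. Of the E5 bins in DMSO, 51.3% were E6 in GSK-LSD1 and 44.4% were still E5. E4, which bordered E5 or E2 at most of its boundaries in DMSO, was the least stable state: 26.8% of its bins were still E4, 38.8% (95% Wilson interval 38.7 to 39.0) had become TSS-type, and 21.6% had become E1. Of the E2 bins, 17.0% were E1 in GSK-LSD1, and these made up 76.6% of all E1 area in that segmentation. Counting E5 and E6 together, little went the other way. TSS-type bins were kept as TSS-type in 95.9% of cases, and 2.36 Mb left the TSS-type states against 39.7 Mb that entered them. With E5 alone the balance turned, with 28.9 Mb leaving and 17.2 Mb entering. Of the area leaving E5, however, 26.7 Mb became E6, so that setting counts a move between the TSS-type states as a loss. Only 0.136 Mb passed from TSS-type to E2 or E3, against 8.03 Mb in the opposite direction. These transitions by state number were tabulated after the data had been seen, because 3 states in DMSO overlapped another number more than their own relative to chance. E4 overlapped E5 at 12.4 and E4 at 11.9 times chance, E2 overlapped E1 at 3.60 and E2 at 3.15, and E1 overlapped E6 and E1 almost alike, at 12.97 and 12.95.

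**Figure D2:**
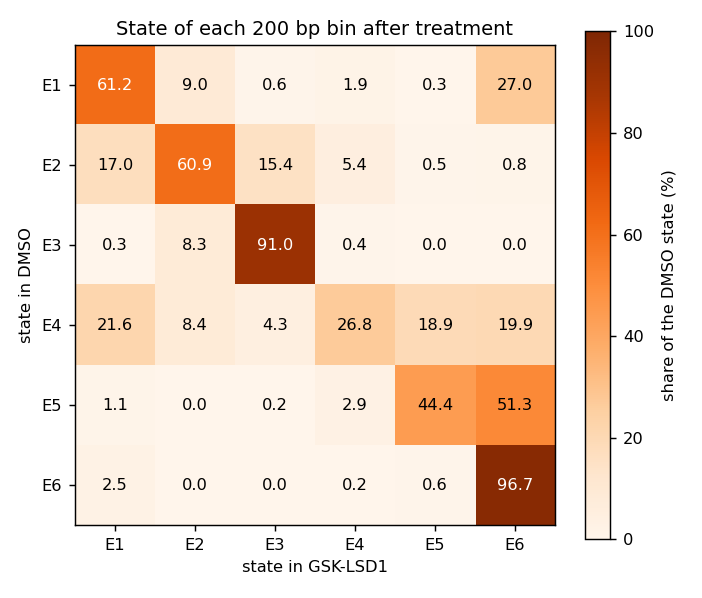
For the bins in each DMSO state (rows), the percentage found in each state in GSK-LSD1 (columns; colour scale 0 to 100%). E5 divided between E5 (44.4%) and E6 (51.3%), and E4 spread over E4, E1, E6 and E5, while 96.7% of E6 was kept.

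Marked chromatin was gained over 173.7 Mb and lost over 89.5 Mb, with 613.6 Mb kept. Bins more than 2.5 kb from every end of an annotated gene of any type made up 86.0% of the gained bins. They made up 80.8% of the lost bins and 75.4% of the kept bins, against 86.6% of the genome. The distal share was thus higher among gained than among kept bins but close to that of the genome. TSS-type bins gave a wider separation: 63.6% of the gained bins (95% Wilson interval 63.4 to 63.9) and 33.5% of the kept bins (33.3 to 33.7) were distal. Lost TSS-type bins were also more distal than kept ones, at 52.9%, so a high distal share was not particular to the gain. Of 30107 TSS-type regions in GSK-LSD1, 10897 overlapped none in DMSO, and 70.4% of those were distal. Of 23705 in DMSO, 1310 overlapped none in GSK-LSD1, and 61.4% of those were distal. These counts rest on E6. With E5 alone, 7771 of 24170 regions in GSK-LSD1 and 10052 of 24673 in DMSO had no overlap, and 57.1% and 57.6% of those were distal. The distal shares of bins were then 47.5% of gained, 39.6% of lost and 23.6% of kept bins. With E5 and E6 together the median region length was 2200 bp in GSK-LSD1 and 1800 bp in DMSO. That direction turned with E5 alone, at 1200 bp in GSK-LSD1 and 1600 bp in DMSO. Counting only regions at least 1000 bp from marked chromatin of the other segmentation changed the balance, to 56754 bins gained and 80632 lost. When E2 was also background, that filter gave 166437 gained and 21336 lost.

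The longest gained regions with no marked bin in DMSO were blocks of E2, and 5 of the 8 longest overlapped no gene. The longest of them spanned 215 kb on chromosome 1 (145563001 to 145778000, GRCm38), 718 kb from Brinp3. Others covered 127 kb (chromosome 3, 136131801 to 136258600) overlapping Bank1, a B cell scaffold protein, and 113 kb over a cluster of 5 olfactory receptor genes (chromosome 2, 111994001 to 112107200). The longest lost block covered 122 kb on chromosome 3 (35452801 to 35575200), 179 kb from Atp11b, and 1 of 116 kb on chromosome 4 (146426801 to 146542400) overlapped the zinc finger genes Zfp981, Zfp992 and Zfp993. With E2 left out, a ranking added after the data were seen, the longest gained regions were E1. They lay within Ssbp2 (43.8 kb; chromosome 13, 91572001 to 91615800), 154 kb from Nrip1 (28 kb; chromosome 16, 76105201 to 76133200), over Dnase2b and Uox (27.4 kb; chromosome 3, 146602201 to 146629600), and within Bbx (26.8 kb; chromosome 16, 50216201 to 50243000). The longest lost E1 region, 20 kb on chromosome 1 (88218801 to 88238800), lay over the Ugt1a cluster of glucuronosyltransferase genes.

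More genes gained than lost a TSS-type state at a gene end. Of 21631 protein-coding genes, 890 (4.11%; 95% Wilson interval 3.86 to 4.39) had E5 or E6 at an end only in GSK-LSD1, 213 (0.985%; 0.862 to 1.13) only in DMSO, and 10973 in both. Myeloid effector genes were among those that gained one. In the granulocyte list these were Cebpe, a transcription factor of late granulocyte maturation, Itgam, which encodes the surface integrin CD11b, the neutrophil proteases Mmp8 and Mmp9, and the chemokine receptor Cxcr2, or 5 of the 17 members without one in DMSO. The count takes only the bin at the gene end. Cebpe already had E5 in DMSO at 54711601 to 54712000, beside the bin of its end at 54712174. With any bin within 1 kb of an end counted, 570 genes gained a TSS-type state and 174 lost one. In the monocyte list Cd86, Adgre1 and Tlr4 gained one (3 of 10), and in the azurophil granule list the myeloperoxidase gene Mpo and the cathepsin G gene Ctsg (2 of 5). Over all protein-coding genes the share was 8.52% of the 10445 without one in DMSO. Shares were higher in some small groups of other lists: Stat3 in the JAK/STAT list (1 of 2), Zmym2 in the LSD1-CoREST list (1 of 2) and the housekeeping genes Hprt and Pgk1 (2 of 3). The antigen presentation list, with Cd80 and Cd86 (2 of 7), was close to the granulocyte and monocyte lists. No gene gained one in the progenitor list (0 of 4), the interferon list (0 of 4) or the 4 lists for other blood or stromal cell types, a difference between lists that was not tested. Cxcl12, Apoa1 and Neurod1, from the stromal and unrelated-tissue lists, had one only in DMSO. With E5 alone as TSS-type, 639 genes gained it and 4925 lost it. Since 213 genes lost both states, most of the 4925 still had E6 at an end.

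Genes of granulocyte differentiation had more TSS-type chromatin after treatment. TSS-type area was chosen for the gene lists after the planned measure, the area of all marked states, had given a median change of 0 kb in each of the 15 lists. Within 20 kb of either gene end, 13 of the 18 list members had more E5 or E6 in GSK-LSD1, 0 had less and 5 were equal. Among all 21631 protein-coding genes, 14296 had more. The median change of the list was 3.1 kb, against 0.4 kb (central 95% range 0 to 1.5) in 10000 random lists matched on DMSO TSS-type area, which is percentile 100 as a description of these 2 segmentations. Itgam went from 2.8 to 14.8 kb, Mmp8 from 4.8 to 16.4 kb, Cebpe from 6.2 to 17.8 kb and Cxcr2 from 0 to 7.4 kb. Other members were less uniform. Ltf (lactoferrin) went from 3.2 to 6.4 kb and Lcn2 from 9.8 to 15.2 kb, but Ly6g, S100a8, Chil3, Retnlg and Cd177 had 0 kb in both. Without matching, the list lay at percentile 96.2, and with E5 alone at 49.7.

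Monocyte and macrophage genes were also high in TSS-type gain against matched genes, with 12 of 18 higher, 1 lower and 5 equal. Against all protein-coding genes they were ordinary: 14296 of 21631 were higher, with a median change of 1400 bp. The median change of the monocyte list was 1.5 kb against 0.2 kb in matched lists (0 to 1.2; percentile 99.2). Fcgr1, the high-affinity IgG receptor, went from 15.6 to 32.2 kb, Cd14, a co-receptor for lipopolysaccharide, from 8.4 to 21.0 kb, and Adgre1, which encodes F4/80, from 0.4 to 8.4 kb. Csf1r, Cx3cr1, Cybb and Adgre4 had 0 kb in both, and Klf4 had 3.6 kb in DMSO and 3.4 kb in GSK-LSD1. The list dropped to percentile 96.0 when random lists were matched on E4 area as well, to 95.3 with 50 kb windows, to 56.4 without matching and to 50.2 with E5 alone.

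Azurophil granule genes, which mark promyelocytes, were all higher (9 of 9), with a median change of 4.8 kb against 2.2 kb in matched lists (0.6 to 4.8; percentile 97.8). Nkg7 went from 6.6 to 13.2 kb, Ctsg from 0 to 6.0 kb, Srgn from 19.8 to 25.4 kb and Mpo from 0.2 to 4.2 kb. Elane and Prtn3, neighbouring genes of neutrophil serine proteases whose windows overlap, both had 11.4 kb in DMSO, and 16.2 and 16.6 kb in GSK-LSD1. This list lay at the edge of the range. It left the upper tail under 6 settings, among them 50 kb windows (percentile 73.9) and E5 alone (0.445).

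All 18 genes of JAK/STAT signalling, the pathway downstream of CSF3R, had more TSS-type chromatin. Their median change was 9.2 kb against 5.4 kb in matched lists (3.8 to 7.3; percentile 99.99). Stat5b went from 20.8 to 33.8 kb, the cytokine gene Osm from 18.2 to 31.2 kb, the feedback inhibitor Socs3 from 23.4 to 35.4 kb and the kinase gene Jak1 from 8.6 to 20.6 kb. The difference was smaller at Jak3, which went from 16.8 to 19.2 kb. E1 and E6 together separated this list furthest, with a median change of 35.7 kb against 16.9 kb (9.1 to 24.8; percentile 100). The TSS-type result lay at percentile 66.4 with 5 kb windows and at 0.005 with E5 alone.

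**Figure D3:**
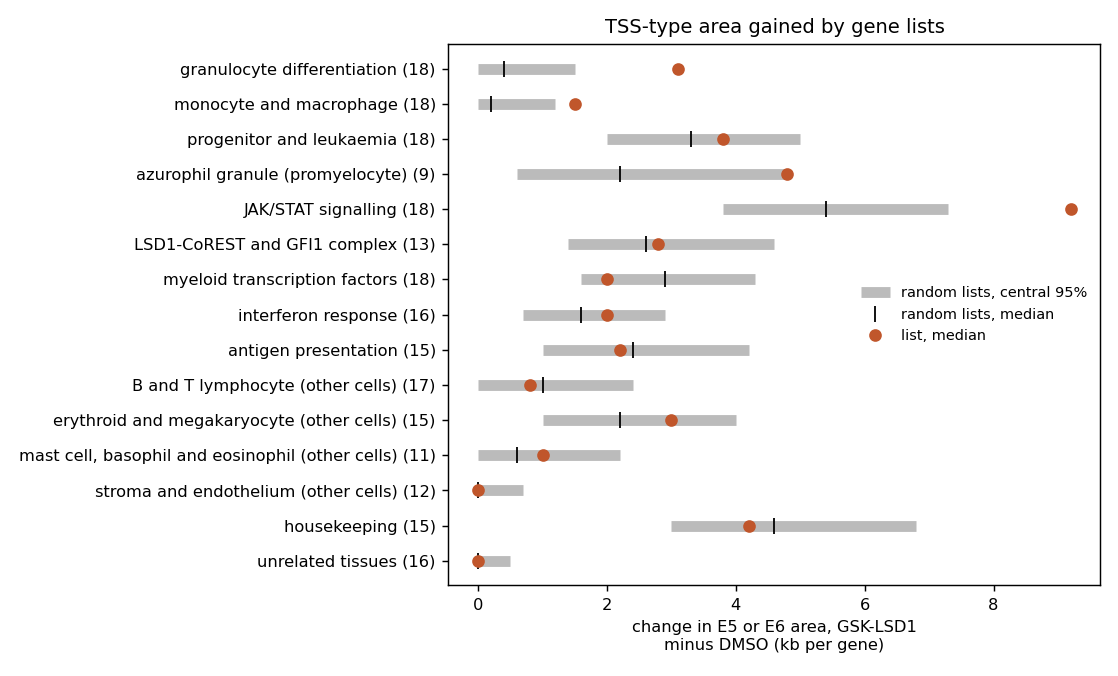
Median change per gene in TSS-type area (E5 or E6; kb, GSK-LSD1 minus DMSO; x axis) within 20 kb of gene ends for the 15 gene lists (orange points, number of genes in parentheses), with the median (black ticks) and central 95% (grey bars) of 10000 matched random lists. The granulocyte, monocyte and JAK/STAT lists lie beyond their grey bars and the azurophil granule list lies at the edge of its bar.

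The other 11 lists lay within the central 95% of random lists in TSS-type gain. Most genes were higher in 9 of them, the exceptions being the stromal and unrelated-tissue lists. In the progenitor and leukaemia list 17 of 18 were higher (percentile 73.3), including the cell cycle kinase gene Cdk6 (29.0 to 41.8 kb), Mecom (8.8 to 18.6 kb), Cd34 (5.0 to 14 kb) and Runx1 (19 to 27.8 kb). Kit, the stem cell factor receptor, had 2.4 and 2.8 kb. In the LSD1-CoREST and GFI1 list 12 of 13 were higher (percentile 55.2), and the repressor genes Gfi1 (5.2 to 22.0 kb) and Gfi1b (10.6 to 25.6 kb) had the largest changes. Myeloid transcription factors lay low at percentile 8.85, with 16 of 18 higher. Spi1, which encodes PU.1, went from 10.4 to 22.8 kb, but Egr1 went from 9.6 to 10.6 kb. Interferon response genes (9 of 16 higher, percentile 73.0) included Usp18 at 4.8 and 15 kb. Antigen presentation genes (11 of 15 higher, percentile 43.4) included Tap2 at 17.4 and 23.0 kb, while H2-Aa had 3.4 and 2.0 kb. Housekeeping genes were higher in 14 of 15 (percentile 31.6), with Pgk1 the exception at 11.8 and 7.8 kb.

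Markers of other cell types did not stand apart in TSS-type gain. Percentiles were 35.9 for B and T lymphocytes (10 of 17 higher), 85.1 for erythroid cells and megakaryocytes (12 of 15), 71.3 for mast cells, basophils and eosinophils (8 of 11), 34.5 for stroma and endothelium (5 of 12) and 42.7 for unrelated tissues (5 of 16). Single members of these lists were high all the same: Pecam1 went from 11.8 to 31.0 kb, Cpa3 from 12.8 to 26.4 kb, Pf4 from 6.4 to 16.0 kb and Rag1 from 5.2 to 14.4 kb. In E1 and E6 area the B and T lymphocyte list had a median change of 11.2 kb against 1.8 kb (percentile 99.5).

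E1 and E6 spread over single genes tied to the drug and to granulocytic maturation, although the granulocyte list as a whole had a median change of 1.5 kb in these states against 2.5 kb in matched lists (percentile 32.1) and the monocyte list lay at percentile 51.7. The 2 states were absent at Cebpa and Csf3r, the cells' own copies of the genes introduced in mutant form. Neither pattern was particular to these genes. Of 21631 protein-coding genes, 12973 had E1 or E6 in their window in at least 1 segmentation. The area was larger in GSK-LSD1 at 12741 genes and smaller at 205. Gfi1 (chromosome 5, 107716655 to 107725805) had 0 kb of E1 or E6 within its window in DMSO and 47.6 kb in GSK-LSD1. Around Cebpe (chromosome 14, 54710363 to 54712174) the same states went from 0.8 to 41 kb, and around Itgam (chromosome 7, 128062640 to 128118491) from 5.4 to 39.2 kb. Cebpa (chromosome 7, 35119293 to 35121928) had no E1 or E6 in either segmentation, and its TSS-type area went from 3.4 to 6.0 kb. Csf3r (chromosome 4, 126023441 to 126044975) also had neither state, with 6.8 and 10.6 kb of TSS-type chromatin in its window. In DMSO that area lay wholly outside the gene, between 126046401 and 126059800. In GSK-LSD1, E5 also lay inside the gene, at 126024001 to 126026800. Kdm1a (chromosome 4, 136550533 to 136602787), the drug target, went from 2.8 to 4.8 kb of TSS-type and from 30.0 to 80.4 kb of marked chromatin, the latter filling its window.

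**Figure D4:**
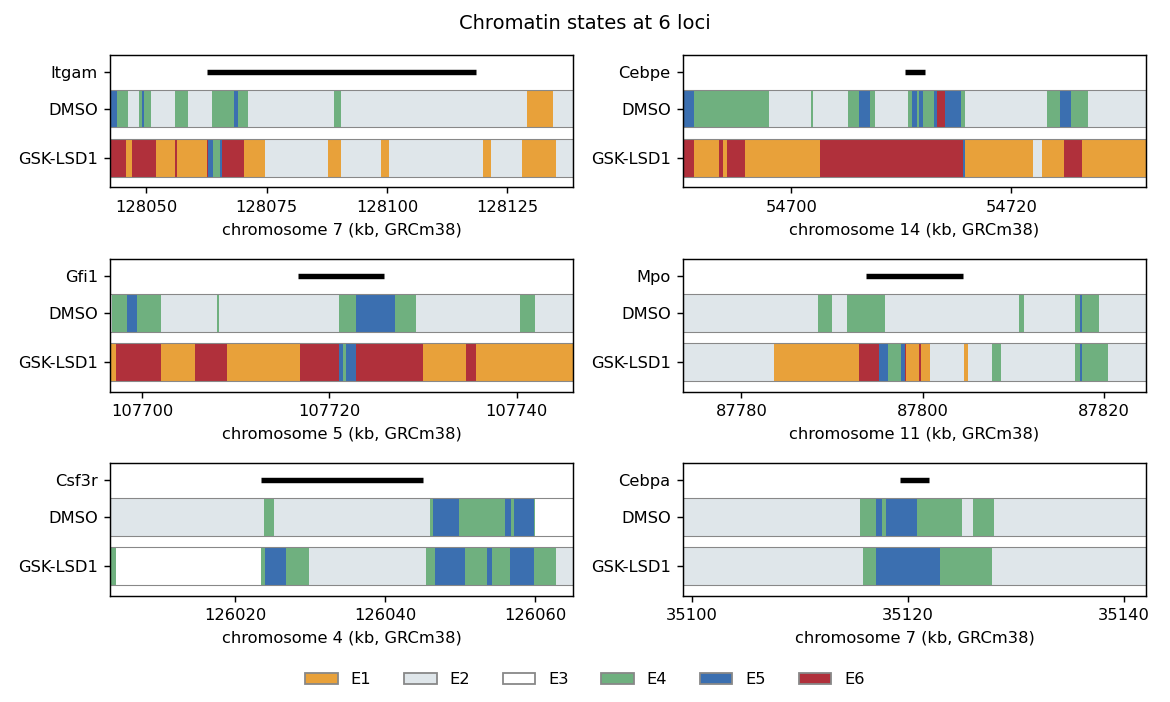
Chromatin states within 20 kb of 6 genes (x axes, position in kb, GRCm38) in DMSO (upper strip) and GSK-LSD1 (lower strip); black bars are the genes and colours are the 6 states. E6 (red) and E1 (orange) replace E2, E4 and E5 around Cebpe, Gfi1 and parts of Itgam and Mpo, while Csf3r and Cebpa show neither state.

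Across the genome, 14296 protein-coding genes had more TSS-type area in GSK-LSD1, 929 had less and 6406 were equal. The 12 largest increases, in a ranking added after the data were seen, included the kinase gene Camkk2 (17.8 to 47.2 kb), Il2ra, the interleukin-2 receptor alpha chain (16.0 to 41.4 kb), Vav1, a guanine nucleotide exchange factor of blood cells (12.6 to 35.6 kb), Irak2 (17.2 to 39.0 kb), Csf2rb2, a beta chain of the interleukin-3 receptor (28.4 to 50 kb), and Pdcd1lg2, the checkpoint ligand PD-L2 (5.0 to 26.4 kb). Gfod1, Susd1, Rubcnl, Agps and Cdh3 were also among them. The largest decreases were smaller, from 26.2 to 14 kb at Sfi1, 5.8 to 2.6 kb at Irx2, 6.8 to 3.8 kb at Prdm16 and 2.6 to 0 kb at Foxf2. With E5 alone, 6186 genes had more and 8668 had less.

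The planned measure, the area of all marked states, could hardly separate the lists. It was higher at 6459 genes, lower at 4547 and equal at 10625. Each of the 15 lists had a median change of 0 kb and lay between percentiles 30.5 and 50.5. The typical matched random list also had a median change of 0 kb, and ties took the middle rank. These percentiles thus say little about the lists. The largest changes were whole windows entering or leaving E2. Ccdc170 went from 0 to 80.4 kb, the interferon-induced gene Herc6 from 5.8 to 80.4 kb and Hgf, which encodes hepatocyte growth factor, from 11.2 to 80.4 kb. Rab3b went from 80.4 to 2.6 kb, Elfn1 from 80.4 to 7.2 kb and the elastin gene Eln from 80.4 to 16.2 kb. Among list members, Retnlg went from 0 to 39.8 kb and S100a9 from 6.6 to 34.4 kb, while Cd177 went from 52.4 to 16.6 kb and Kit from 55.4 to 15.4 kb. Ifit2 went from 10.4 to 66.2 kb and Ifit3 from 6.8 to 46.0 kb. The class II genes H2-Aa and H2-Eb1 went from 10.4 to 45.4 kb and from 16.2 to 51.0 kb.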

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

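Which libraries produced a difference cannot be separated by any setting, since each mark had 1 library per treatment; no paired analysis was possible because no group has more than 1 library per mark. Depth is unknown and limits every value. The settings chosen after seeing the data were E5 alone through a limit of 10 over both ends, chromosomes 1 to 19, the combined E2 and 1000 bp filter, E1 and E6 alone, and every setting for TSS-type lists and for the genes with more or less TSS-type area (windows of 5 and 50 kb, short segments). Lists are placed against the central 95% range of random lists. Motif and sequence-composition results and their alternatives were not run. The cause of each change below was not tested unless the setting itself gives it. The ratios of E1 and E6 stayed above 9 and those of E4 and E5 below 1 under every setting run. TSS-type coverage reversed, to a ratio of 0.774, when the TSS-type limit was raised to 20, or to 10 over both ends, which by construction leaves E5 alone. Under that limit the 26.7 Mb that went from E5 to E6 counts as lost. Other marked chromatin then had a ratio of 1.15 and 4925 genes lost a TSS-type end. In addition, 6186 genes had more and 8668 less TSS-type area, 0 lists lay above and 2 below the range (JAK/STAT reversed to 0.005, azurophil to 0.445), and granulocyte and monocyte lists lay at 49.7 and 50.2. With E2 also as background the marked ratio was 1.95, other marked 2.15, lost bins 53186, overlap 45.8%, distal shares 79.9% gained and 68.5% lost, with 14766 genes higher and 1845 lower. Then 4 lists lay above the range in all-marked area (azurophil, JAK/STAT, lymphocyte, mast cell) and 1 below (unrelated tissues). Only regions 1000 bp away gave 56754 bins gained, 80632 lost, 95.7% overlap and distal shares of 90.6% and 84.6%; with E2 as background too, 166437, 21336, 77.9%, 84.7% and 75.8%. Distal shares of gained and lost bins were 94.0% and 91.5% beyond 1 kb, and 57.9% and 46.9% beyond 10 kb. With short segments as background they were 85.8% and 80.5%, the overlap 69.7% and the E5 ratio 0.769. Every sequence gave an E3 ratio of 0.958. Chromosomes 1 to 19 gave ratios of 1.11 marked, 1.07 other marked, 0.902 for E2, 0.955 for E3, 0.807 for E4 and 0.767 for E5, an overlap of 70.3% and 86.2% of gained bins distal. Gene ends gained a TSS-type state at 570 genes within 1 kb, and at 1690 (320 lost) over all annotated genes. TSS-type area alone gave 14296 genes higher and 929 lower, and other marked states alone 11452 lower. In all-marked area 1 list (unrelated tissues) lay below the range with 50 kb windows, and 1 with the mean, and 3 lists lay above in E1 and E6. In TSS-type area the granulocyte list lay at 96.2 and the monocyte list at 56.4 without matching. With 50 kb windows the monocyte list lay at 95.3 and the azurophil list at 73.9. The azurophil list lay at 92.4 with the mean and at 97.45 with 50 matching bins. With 5 kb windows, 2 lists stayed above, with azurophil at 90.9 and JAK/STAT at 66.4. Matching on E4 left 2 above, with monocyte at 95.955 and azurophil at 92.8. Matching on GSK-LSD1 placed 1 list below (myeloid transcription factors). Leaving out each chromosome gave ratios of 9.55 to 9.99 for E1, 0.901 to 0.918 for E2, 0.954 to 0.959 for E3, 0.807 to 0.819 for E4, 0.767 to 0.782 for E5, 9.38 to 9.78 for E6, 1.64 to 1.65 for TSS-type, 1.11 to 1.13 for marked and 1.06 to 1.08 for other marked chromatin. It gave 792209 to 843338 bins gained, 407791 to 444664 lost and an overlap of 69.3% to 70.3%.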

Other observations

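The tests of library sensitivity, of LSD1 inhibition, of weak marks, of base composition and of developmental transcription factors were chosen after the results had been seen, as were the settings of the TSS-type lists; those of overlapping windows, matching, E4 area and the conversion of E2 to E1 were set out before their results.

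When E6 is counted with E5, 4 of the 12 genes with the largest decreases in TSS-type area encode developmental regulators. Pax3, a factor of neural crest and muscle, went from 5.8 to 3.4 kb, Irx2 from 5.8 to 2.6 kb, Foxf2 from 2.6 to 0 kb and Prdm16 from 6.8 to 3.8 kb. A TSS-type state at a gene end was lost at 14 of the 135 genes of homeobox, forkhead and similar families that had one in DMSO, 10.4%, against 1.90% of the 11186 protein-coding genes that had one. The 4 named genes prompted the list; without them 11 of 132 (8.33%) lost one. The contrast turned with E5 alone, where 29 of 132 family members (22.0%) and 4925 of 10540 protein-coding genes (46.7%) lost it. Ends that went from E5 to E6 count as lost there, so that contrast does not measure loss of a TSS-type end. Over all 333 members of these families, 206 were higher, 37 lower and 90 equal, and the median change of 0.8 kb lay at percentile 3.19 of matched lists (0.8 to 1.4), inside the range, and at 4.56 without the 4 genes. No separate behaviour of these families is shown: the list was drawn up after the decreases had been seen, and the median change lay inside the range of matched lists.

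The change in marked chromatin and in E2 differed with gene density. In 1 Mb windows without protein-coding genes, marked chromatin went from 1.89% to 3.42%, a ratio of 1.82, and in windows with 20 or more genes from 60.2% to 60.1%, a ratio of 0.998. It went from 12.8% to 17.4% with 1 to 4 genes, from 31.8% to 37.1% with 5 to 9 and from 49.6% to 51.0% with 10 to 19. The ratio thus fell with gene density, but the rise in percentage points was largest with 5 to 9 genes. The gene-free windows also lost a larger share of their E2: 27.7% of the DMSO E2 bins there became background, against 13.04% in the densest windows, while 1.94% and 13.05% of the background bins became E2. On chromosome X, E2 went from 1.30% to 3.24%. E2 coverage was higher in GSK-LSD1 on 2 autosomes, 13 and 18, by 0.985 and 0.198 percentage points, and lower on the other 17. On gene-dense chromosome 11 it fell by 7.18 points while E1 went from 1.04% to 8.19% and background from 56.2% to 54.9%.

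States E1 and E6 covered 9.72 times more of the genome in GSK-LSD1, and in both segmentations E1 and E6 shared 0 boundaries with background. State numbers need not stand for the same marks in both segmentations. Relative to chance, E1 in DMSO overlapped E6 in GSK-LSD1 about as much as E1, although more of its bins were E1. A general gain in sensitivity of all 3 GSK-LSD1 libraries stays open: 12.7% ± 1.70 (SD over autosomes; range 9.01 to 15.1) of marked DMSO bins were background in GSK-LSD1, where nearly none would be lost, but most of these were E2, and the share was 2.33% ± 0.513 without E2. Lost regions at least 1000 bp from marked chromatin of the other segmentation made up 2.29% of the marked DMSO bins, which does not settle it. Under that filter more bins were lost than gained with E2 (80632 and 56754), and fewer without it (21336 and 166437). A more sensitive library of 1 mark, if E1 and E6 share one, also stays open: 91.6% ± 3.12 of the DMSO E1 or E6 bins were E1 or E6 in GSK-LSD1, but any cause that enlarges these states around their DMSO positions would keep them too. LSD1 inhibition itself would also give a ratio above 1 (9.72 here), and with 1 library per mark and treatment it cannot be told apart from a difference between libraries.

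Of the 4 lists with high TSS-type gain, 4 stayed above the central 95% of random lists with 1 member per group of overlapping windows, which argues against neighbouring genes counted several times. Matching in 50 bins left 3 of the 4, losing the azurophil list narrowly at 97.45. Matching on E4 area as well left 2, granulocyte and JAK/STAT: it raised the median of random lists from 0.2 to 0.6 kb for the monocyte list, whose own was 1.5 kb (percentile 95.955), and from 2.2 to 3.2 kb for the azurophil list, whose own was 4.8 kb (92.8), so the part of E4 in these 2 stays open. Weak marks already present at these genes and brought over the threshold by a more sensitive library could give the same picture, and the housekeeping list at percentile 31.6 does not settle this, because its genes were strongly marked already. Weak marks and an effect of LSD1 inhibition cannot be told apart here.

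Over the 19 autosomes, which are not replicates, the change in E2 share and gene density had a Spearman rho of −0.791; for all marked chromatin rho was −0.482. Conversion of E2 into E1 on gene-dense chromosomes does not remove the relation: with those bins added back, rho was −0.623. A base-composition bias that differed between the libraries may account for it, since gene-dense chromosomes are richer in G and C, but gene density is only a proxy and no genome sequence was used here. That bias and an effect of the drug cannot be told apart.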
